A study of Mus musculus with 6 samples.

How the data were processed

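Small RNA was sequenced from spinal cord of C57BL/6 mice at 8 weeks of age, in 3 libraries from mice with traumatic spinal cord injury (TSCI) and 3 from mice with laminectomy alone (sham). Per the labels' protocols, 48 male mice were assigned at random to both arms, as 3 sets of 8 mice per arm. The injury was a weight-drop contusion of moderate severity after removal of the vertebral laminae at thoracic levels 8 to 10, under 3% pentobarbital. The time between injury and tissue collection is not given in the sources used here, and the labels do not say whether a library pooled the 8 mice of a set. Total RNA was extracted with Trizol, and about 5 µg went into Illumina TruSeq small RNA libraries that were sequenced on an Illumina HiSeq instrument. The protocol text speaks of 9 libraries, whereas 6 are listed in the series as used here.

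One table was analysed. Per the labels' protocols, the authors passed the reads through ACGT101-miR, an in-house program of LC Sciences, which removed adapter dimers, junk and low-complexity reads, the abundant structural RNA families and repeats. Per the file headers, the authors then matched reads to miRBase, the registry of published miRNAs and their hairpin precursors, and to the genome and expressed sequence tags, and sorted the hits into 6 categories. The submitters' processing notes name the mouse build mm10. The aligner, the miRBase release, the mismatches allowed and any minimum read count are not given in the sources used here. The deposited values are numbers of distinct miRNAs and of distinct precursors in each category, for each library and for all libraries together. They are not reads, they are not scaled to sequencing depth, and the table names no single miRNA, so no expression level, fold change per miRNA or genome position could be given and no count model applied. The numbers of reads behind the libraries are not given in the table, so the depth is unknown, and no interval that needs it was computed. A number of distinct miRNAs depends on depth, since more reads reveal more rare species.

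Per the file headers, category gp1a holds reads that match the miRBase entries the file calls specific, with precursors that also map to the genome or expressed tags. Category gp1b meets the same conditions with other selected miRBase entries. In gp2a the matched precursor does not map to the genome, but the read does, and the surrounding genome sequence may fold into a hairpin. In gp3 neither the precursor nor the read maps to the genome. In gp4 the read matches no selected precursor, but maps to the genome at a place that may fold into a hairpin. The criterion of gp2b was not used here, and what defines that category is left open. The table does not mark which categories count as known or predicted. The comparisons planned for known and predicted miRNAs were therefore made on gp1a and on the sum of the 5 other categories, gp2b included.

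The table names its libraries con and syz, 3 of each, and no label uses either name. The con columns were read as control, which is the sham group, and the syz columns as the TSCI group because it is the only other group. This reading is an inference from the names, and the sign of every difference between sham and TSCI rests on it, while the tests are two-sided and do not. The libraries are therefore called con and syz throughout. Their numbers were not tied to the replicate numbers of the labels. Of the 2 measures per library, the number of distinct miRNAs was used, and the 6 per-library columns of precursors were not used, to keep 1 column per library where columns are tied to a group only. The planned comparison of precursors was therefore not made, by choice. From the authors' totals over all libraries, both measures were used.

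Sets were compared by the difference of means, syz minus con, with an exact two-sided permutation test over all 20 assignments of the 6 libraries. With 3 against 3 libraries this exact test cannot go below p = 0.10, so no comparison could pass 0.05 in it. Tests that assume normally distributed values have no such floor and were not used at this number of libraries, and each difference is set against the pooled SD or the SDs of the sets instead. By chance, 10% of such comparisons separate without overlap. The range of the 9 differences between 1 syz and 1 con library was taken as a 90% interval for a shift between the sets. Its level is exact only if the libraries are independent and the sets differ by a shift alone. The con libraries spread more widely than the syz libraries in all 10 comparisons of category numbers and summary values (SD 71.3 against 18.6 for the sum), so the level is approximate. Outside those 10, the gp2a and gp3 shares of a library's sum spread less in con, with SDs of 0.150 and 0.234 against 0.223 and 0.263 in syz. Benjamini-Hochberg adjustment covered the 6 categories as one family and the 4 summary values as another. Those 4 were the sum over all categories, gp1a, the sum of the other 5, and the share of the other 5 in a library's sum. Shares of single categories in a library's sum were adjusted apart from these, as one family with gp2b in the sum and another without it. A sum over categories counts a miRNA more than once if it is listed in more than one. The labels do not say that libraries of a group came from separate pools of animals, so the p-values compare these libraries only and may not extend to other animals.

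The alternatives were leaving out each library, medians, the log2 scale, shares of a library's own sum and other groupings of the categories, all fixed before the data were examined. Leaving gp2b out of the sums, with and without con1, was added after the data were seen. The rule for named genes, also fixed beforehand, was to report every category and name no miRNA if the table held categories only. Planned lists of miRNAs of myeloid cells and inflammation, neurons, oligodendrocytes, astrocytes and other glia, red blood cells and muscle could not be scored. Computations used Python 3.11.15 and figures matplotlib 3.10.9.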

Results

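The study profiled miRNAs, the short RNAs that repress target messenger RNAs, in mouse spinal cord with and without traumatic injury. The 3 small RNA libraries of injured and 3 of sham cord were analysed from a summary of distinct miRNAs per annotation category. Libraries are named con and syz after the table. Con was read as the sham group and syz as the injured group, which no label states. The numbers are distinct miRNAs, not reads, and the sequencing depth of the libraries is unknown.

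Over all 6 libraries together, the authors' totals came to 1228 distinct miRNAs and 1026 distinct precursors, summed over the 6 categories. Most of the repertoire was in gp1a, the miRBase entries called specific with precursors placed on the genome, which held 809 miRNAs or 65.9% of the sum. Category gp2b, whose criterion was not used here, came next with 163 miRNAs (13.3%). There were 94 miRNAs in gp4, the reads with no selected miRBase precursor whose genome surroundings may form a hairpin. Category gp2a, with reads but not precursors placed on the genome, held 81, and gp3, with neither placed, held 65. Category gp1b, other selected miRBase entries placed on the genome, held 16. In gp1a the 809 miRNAs came from 559 precursors. In gp2b the order was the other way, with 202 precursors for 163 miRNAs. It was also so in gp4 (100 for 94), gp2a (87 for 81) and gp3 (66 for 65). A hairpin precursor can yield a mature miRNA from each of its arms, and several precursors can yield the same mature miRNA.

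Individual libraries recovered most of gp1a and much less of gp4. Between 80.0% and 88.6% of the authors' total for gp1a was found in any one library, and between 75.4% and 84.6% of that for gp3. For gp4 the range was 33.0% to 56.4%. The widest range of the 6 categories was in gp2b, from 39.3% to 75.5%.

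**Figure D1:**
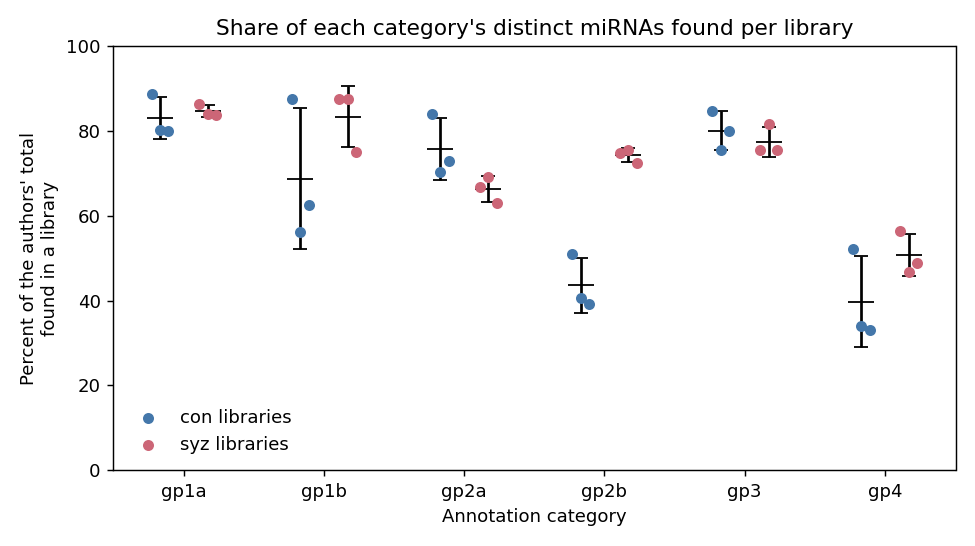
Percent of the authors' total of distinct miRNAs in each category that was found in a library, for the 3 con (blue) and 3 syz (red) libraries; points are libraries, and black bars give the mean and SD. Both sets lie near 80% in gp3, whereas gp2b was at 74.2% ± 1.62 in syz and 43.6% ± 6.41 in con (SD, n = 3 each).

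The first comparison asked whether the size of the miRNA repertoire differed between the sets. The syz libraries held 972 ± 18.6 distinct miRNAs over all categories and the con libraries 904 ± 71.3 (SD, n = 3 each), 7.52% more in syz. The sets overlapped, with 954 to 991 in syz and 862 to 986 in con, and the difference of 68 was not significant (exact two-sided permutation p = 0.30, adjusted p = 0.40 over 4 summary values). The 90% interval ran from -32 to 129. One con library, con1, held 986 miRNAs, while con2 and con3 held 862 and 863. Without con1 the difference was 109, and the smallest p that test allows, 0.10 by exact permutation, was reached. Leaving out any other library gave 47.2 (without con2) to 76.8 (without syz3), with an exact permutation p of 0.30 or 0.40. Leaving out gp2b, a choice made after seeing the data, took the difference from 68 to 18 (exact permutation p = 0.60), and leaving out con1 as well gave 53.2 (p = 0.10).

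With all 6 libraries, the gp1a repertoire was not distinguishable in size between the sets. It held 686 ± 11.6 miRNAs in syz and 671 ± 39.8 in con (SD, n = 3 each), a difference of 14.7 with a 90% interval from -39 to 52 (exact permutation p = 0.60, adjusted p = 0.60). The con library con1 held the most of all 6, 717, against 649 in con2 and 647 in con3, and the syz libraries lay between, at 678 to 699. Leaving out con1 widened the difference to 37.7, with every syz library above con2 and con3 and the smallest p of that test (exact permutation p = 0.10). Leaving out con2 or con3 narrowed it to 3.67 or 2.67. Without syz1 it was 8.

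The 5 categories other than gp1a together held more miRNAs in every syz library than in any con library. The means were 286 ± 8.72 in syz and 233 ± 31.5 in con (SD, n = 3 each), a difference of 53.3 with a 90% interval from 7 to 79. As a share of a library's own sum they made up 29.4% ± 0.484 in syz and 25.7% ± 1.40 in con. Both comparisons gave the smallest p that this test allows (exact permutation p = 0.10, adjusted p = 0.20), and both differences were larger than the pooled SD of the libraries, 23.1 miRNAs and 1.05 percentage points. With all 6 libraries, most of both differences lay in gp2b. Without that category the difference in number was 3.33 (exact permutation p = 0.90) and the difference in share 0.030 percentage points. These values depended on con1, since without it and gp2b they were 15.5 (exact permutation p = 0.20) and 0.65 percentage points (p = 0.30). The 3.33 was a net value. In it, differences of 10.3 in gp4 and 2.33 in gp1b were offset by -7.67 in gp2a and -1.67 in gp3.

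By category, the numbers of the sets stood apart in gp2b and, by a narrow margin, in gp2a. In gp2b the syz libraries held 121 ± 2.65 miRNAs and the con libraries 71.0 ± 10.4 (SD, n = 3 each), which is 1.70 times as many in syz. The 3 syz libraries held 118 to 123 and the 3 con libraries 64 to 83, and the 90% interval of the difference of 50 ran from 35 to 59. In gp2a the order was the reverse, with 53.7 ± 2.52 in syz and 61.3 ± 5.86 in con, or 0.875 times as many in syz. The highest syz library held 56 and the lowest con library 57, and without con1 the difference of -7.67 shrank to -4.33. The gp2b difference was far larger than the pooled SD of 7.62, and that of gp2a was larger than its pooled SD of 4.51. Each gave the smallest p of the test (exact permutation p = 0.10, adjusted p = 0.30 over 6 categories). Sets without overlap arose in 2 of the 6 categories, where chance gives 10% for any one comparison. The categories were counted in the same libraries and are not independent, so this is no test against chance. As a share of a library's own sum, gp2a was further apart than in number, at 5.35% to 5.77% in syz and 6.61% to 6.90% in con. With gp2b left out of the sum the gp2a shares still did not overlap, at 6.10% to 6.61% and 7.16% to 7.53% (exact permutation p = 0.10 for both, adjusted p = 0.15 and 0.33).

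The numbers in the other categories overlapped between the sets. In gp4 the means were 47.7 ± 4.73 in syz and 37.3 ± 10.1 in con, a difference of 10.3 with a 90% interval from -5 to 22 (exact permutation p = 0.30, adjusted p = 0.60). The con values were 49 in con1, 32 in con2 and 31 in con3, and without con1 the difference was 16.2 (exact permutation p = 0.10). Leaving out any other library gave 7.17 (without con3) to 12.2 (without syz2), with an exact permutation p of 0.30 to 0.50. In gp1b the means were 13.3 ± 1.15 in syz and 11 ± 2.65 in con (exact permutation p = 0.40, adjusted p = 0.60). Without con1 the difference of 2.33 became 3.83 (exact permutation p = 0.10), and without con2 1.33 (exact permutation p = 0.70). The category gp3 had 50.3 ± 2.31 miRNAs in syz and 52.0 ± 3.00 in con (SD, n = 3 each), a difference of -1.67 with a 90% interval from -6 to 4 (exact permutation p = 0.70, adjusted p = 0.70). Without con1 that difference was -0.17. As shares of a library's own sum, gp3 and gp1a did not overlap. The gp3 share was 4.94% to 5.46% in syz and 5.58% to 6.03% in con, and the gp1a share 70.1% to 71.1% and 72.7% to 75.3% (exact permutation p = 0.10, adjusted p = 0.15 for each). Both overlapped once gp2b was left out of the sum (exact permutation p = 0.30 for gp3 and 1.0 for gp1a). The gp2b share was 12.3% to 12.7% in syz and 7.42% to 8.42% in con. Shares of a library add up to the whole, so a larger gp2b share lowers the others. The adjusted p of 0.15 therefore adds no separate support. None of the 10 comparisons of category numbers and summary values, which count gp1a in both families, passed an adjusted p of 0.05, which this exact test cannot reach with 3 against 3 libraries. Nor did any share of a single category, and those shares are not among the 10.

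**Figure D2:**
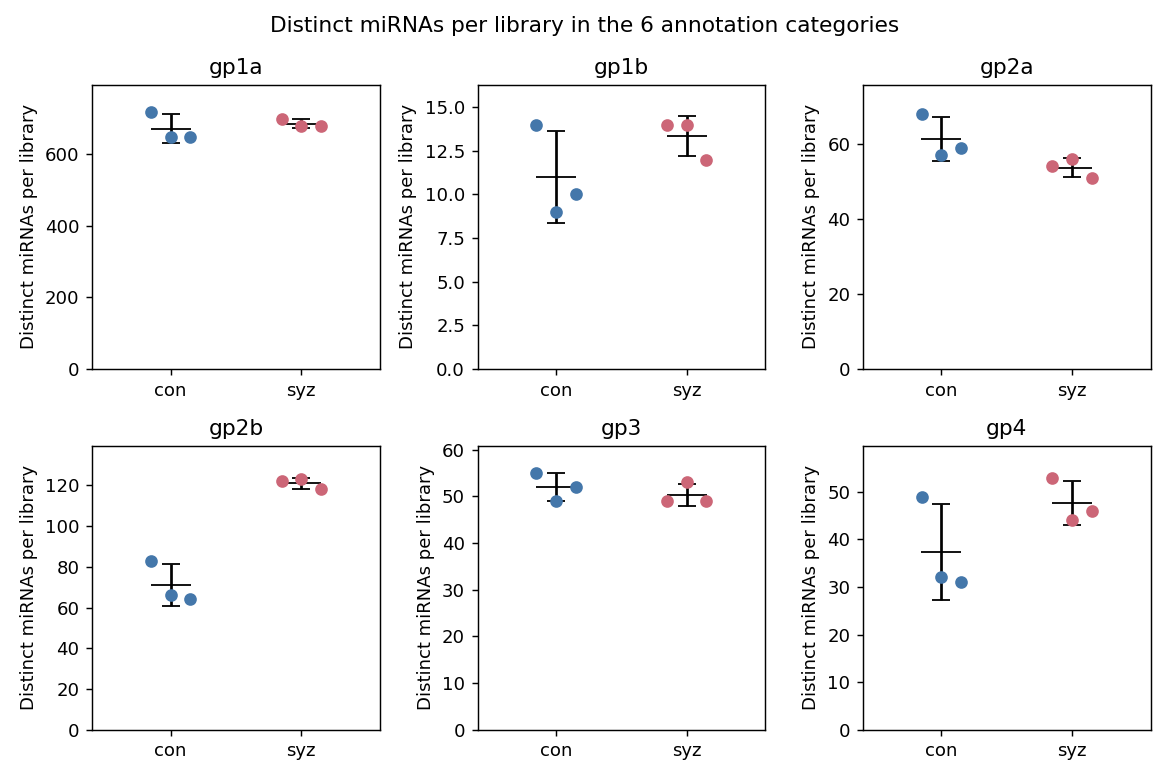
Number of distinct miRNAs per library (vertical axis, from 0, scaled per panel) in each of the 6 categories for the 3 con (blue) and 3 syz (red) libraries; points are libraries, and black bars give the mean and SD. The sets are far apart in gp2b (118 to 123 in syz, 64 to 83 in con), and in gp1a, gp1b, gp3 and gp4 they overlap.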

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

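Of 102 alternative values for the 10 comparisons, 91 were planned and 11, those without gp2b, were added after seeing the data; gp1a is counted both as a summary value and as a category. The direction held in 99, and none passed p = 0.05, which the exact permutation test cannot reach here (its smallest p is 0.10), so that test says nothing on the stability of calls. The 3 reversed values were shares of gp1a, 1 of them listed under both. As a share of the library's own sum, gp1a was lower in syz by 3.76 percentage points (-3.76), although its number was higher by 14.7. The share of gp1a and that of the other 5 categories add up to the whole, so this is the larger share of the others seen from the other side. Without gp2b in the sum it was -0.030. The library con1 moved most values: without it the differences in the sum (68), gp1a (14.7), gp1b (2.33) and gp4 (10.3) grew to 109, 37.7, 3.83 and 16.2. Each of these reached the smallest p of that test (exact permutation p = 0.10). Since con1 was the highest con library in all 6 categories, leaving it out could only raise syz minus con. The categories gp1a, gp1b and gp4 are also parts of the sum, so these p-values are not separate results. The differences in gp2a and gp3 shrank to -4.33 and -0.17 without con1. The gp3 difference was -3.17 without con2, -3 without syz2 and -1 without syz1 or syz3. The gp2b difference stayed between 46.5 and 56 whichever library was left out. Medians gave 107 for the sum, 31 for gp1a, 4 for gp1b, -5 for gp2a and -3 for gp3. Counting gp4 alone in place of the 5 other categories gave 10.3, and counting all categories but gp4 with gp1a gave 57.7. No paired analysis was possible because the columns could be tied to a group but not to the numbered replicates of the labels. The precursor alternatives were not run because 1 measure per library was used, by choice, and the table has no total line to set against the sums.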

Other observations

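In this part, the explanations and the differences set against them were chosen after the values were seen, although some of those differences were planned comparisons.

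The gp2b category held 121 miRNAs in syz against 71.0 in con. Deeper sequencing of the syz libraries as the sole cause would not lower another category, but gp2a was lower in syz, with a difference of -7.67 (pooled SD 4.51). Without con1 it was -4.33 (pooled SD 2.21, exact permutation p = 0.20), and the nearest libraries differed by only 1 miRNA. Also without con1, gp2b, gp1a, gp4 and gp1b were higher in syz by 56, 37.7, 16.2 and 3.83, a direction that greater depth would also give. The gp3 difference was then -0.17. A part played by depth is not excluded, nor is depth together with a shift of miRNAs out of gp2a. A shift of miRNAs from gp2a to gp2b would need gp2a to lose what gp2b gained, and the differences of -7.67 and 50, both already reported, leave 42.3 that gp2a did not supply. Small RNA of another organism stays open: gp3, whose reads match miRBase but not the genome, differed by -1.67, but without the criterion of gp2b it cannot be said in which category such RNA would fall. Also open are chance, which the exact test cannot exclude with 3 against 3 libraries although the difference of 50 was far above the pooled SD of 7.62, and injury, if syz is the injured set; one hypothesis is that injured cord may hold a wider range of the small RNAs that gp2b collects, which needs the criterion of gp2b and the sequences to test.

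The library con1 held more distinct miRNAs than con2 and con3 in 6 of the 6 categories. Deeper sequencing or higher yield of con1 may account for this, since either raises all categories together; the reads per library would be needed to check it, and the numbers of distinct miRNAs alone give no depth. In gp2b con1, with 83, was still below the lowest syz library, with 118, although its gp1a number of 717 was above the highest syz value of 699. The syz library of the same number, syz1, was the highest of its set in the sum (991), gp1a (699) and gp4 (53). It was level with syz2 in gp1b, and syz2 was the highest in gp2a, gp2b and gp3. Whether equal numbers mark a shared batch is not known.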
